A study of Homo sapiens with 12 samples.

How the data were processed

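Total RNA of the H1 line was extracted with Trizol, and 100 ng per sample was amplified and labelled with Cy3, per the labels. Each sample was hybridized to 1 array of an Agilent whole human genome design, 45015 spots in all. Spot signals were extracted with Feature Extraction 10.5.1.1, per the file headers. The deposited scanner files give each spot's processed signal as a linear intensity, with spatial and multiplicative detrending and surrogate values for dim spots switched on, per the file headers. They also give mean spot and local background intensity and quality flags. The deposited values on the log2 scale cover the same 12 arrays, and the columns of that table have almost the same quartiles, as after quantile normalization, with a median of 6.99 to 7.00, and no header says how they were made. It was used only as an alternative. Probe coordinates are on hg18, per the file headers.

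Of the spots, 1639 were controls and 43376 carried 41000 probes. Probes were named through the reference table of RefSeq genes, 23958 by accession, 2755 by current symbol and 1032 by an older symbol; 13255 had no symbol and were kept as unnamed features. Spots flagged as uneven or as population outliers (38 to 122 per array) were left out, and the spots of a probe were averaged on the log2 scale. No spot was saturated. The log2 processed signal of each array was reduced by its 75th percentile over non-control probes. The probe with the highest mean over the 12 arrays stood for its gene. A gene was tested where its probe was well above background, as flagged in the deposited files, on all 3 arrays of at least 1 group.

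Arrays were grouped by their source names into EB9 and EB20 at day 0 and day 18. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, all 12 arrays), with two-sided moderated tests and Benjamini-Hochberg adjustment over the genes of a comparison; "called" means an adjusted p below 0.05. The 5 labelled comparisons, the tests, the alternatives and the 30 gene lists were chosen before the data were examined. The lists were tested with camera at a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry, adjusted over the lists of a comparison. After the data had been seen, the same fit was run on 4 sets of 3 arrays defined by the letter and last digit of the title, with 5 comparisons. Genes to name were chosen by a rule fixed beforehand: the 10 largest changes in each direction among called genes with a symbol and no overlap between the groups, the largest changes in each list (up to 4 called and 2 uncalled), all globins, GATA1, KLF1, POU5F1 and the called enucleation list members. Of the genes that rule gave, the text names a part. Where no probe of a gene was well above background on any array of 1 group, a lower bound is given.

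Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the deposited value table, no filter on dim probes or a filter over all 12 arrays, the mean of all probes of a gene, eBayes with trend and robust settings, array weights, slide as a random or fixed block, only the groups compared, and each array left out in turn. The title number shared by a day 0 and a day 18 array was tried as a replicate block. Deviations from the group means correlated at r = 0.742 to 0.867 across genes in all 6 pairs of arrays, above the limit of 0.1 fixed beforehand. The arrays of such a pair also share the last title digit, by which every labelled group splits. This r is therefore no evidence of shared cultures, and the main counts come from the fit without the block. For title sets, r ran from -0.062 to 0.180 between arrays with the same middle digit. There 2 of 18 pairs passed the limit, so these were not treated as paired. Added after the data had been seen were normexp with outlying backgrounds replaced, the last title digit as a covariate, every alternative for the title sets, and the average of arrays B21 and B31. Between B21 and B31 the spread per array over 8101 bright probes was 0.05 on the log2 scale, and spots of 1 probe within an array varied by 0.05 to 0.07 in their set, so the 2 arrays differed no more than spots of 1 array do; they were kept as 2 samples.

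The fit was tested on simulated data with each gene's spread as on the real arrays and noise drawn independently for each gene. In the labelled groups the real spread is shared by many genes, since the arrays split by last title digit. The simulation does not hold that split, so its results for labelled groups apply to independent noise only. For EB20 versus EB9 at day 18, the fit recovered 12.0%, 38.0%, 68.0% and 90.0% of genes changed by 1, 2, 4 and 6 on the log2 scale among 21540 genes, with 5 false calls among 21340 unchanged genes. For title letter B versus A in digit 3, it recovered 68.0%, 96.0%, 98.0% and 100% among 25246, with 4 false calls among 25046. Tables were read with data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.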

Results

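RNA from the human embryonic stem cell line H1 was measured on 12 one-colour microarrays. The labels sort them into 4 groups of 3 arrays: EB9 and EB20, each at day 0 (embryoid body cells) and at day 18 of erythroid culture. The labels do not define the numbers in EB9 and EB20. The series concerns enucleation, the step at which a maturing red cell precursor expels its nucleus. Of 41000 probes, 27567 to 34719 lay well above background on an array, and the 75th percentile of signal ran from 547 to 1145 intensity units. The number of arrays limits the precision of every value. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so every p-value here measures the spread between these samples. Gene levels are log2 signal minus the array's 75th percentile. Changes are log2 differences ± their standard error, with n = 3 arrays per group. Wherever a named gene is said to have risen or fallen between 2 groups, all 3 arrays of 1 group lay on the same side of all 3 of the other. Counts of list genes that rose or fell are counts of called genes, without that condition.

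Erythroid and embryonic marker genes did not follow the labelled groups. They followed the last digit of the sample titles, which is 1 or 3, and both digits occur in every labelled group. Each EB9 group holds 2 arrays of digit 1 and 1 of digit 3, and each EB20 group holds 1 and 2. All titles of arrays labelled day 0 begin with A, and all those labelled day 18 with B. ALAS2, which encodes the first enzyme of heme synthesis in red cell precursors, ran from 9.10 to 9.68 on the 6 arrays whose titles end in 3 and from -0.51 to 3.54 on the 6 that end in 1. GATA1, the erythroid transcription factor, ran from 3.45 to 3.76 and from -5.16 to -2.21. COL1A1, a collagen of stromal cells, lay the other way, from -7.21 to -6.37 on digit 3 arrays and from 4.72 to 5.88 on digit 1 arrays. The pluripotency factor POU5F1 ran from -1.56 to -1.10 and from 0.80 to 2.56. Within the arrays labelled EB9 day 0, ALAS2 stood at -0.26, 9.33 and 0.08, in title order A11, A13 and A21.

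**Figure D1:**
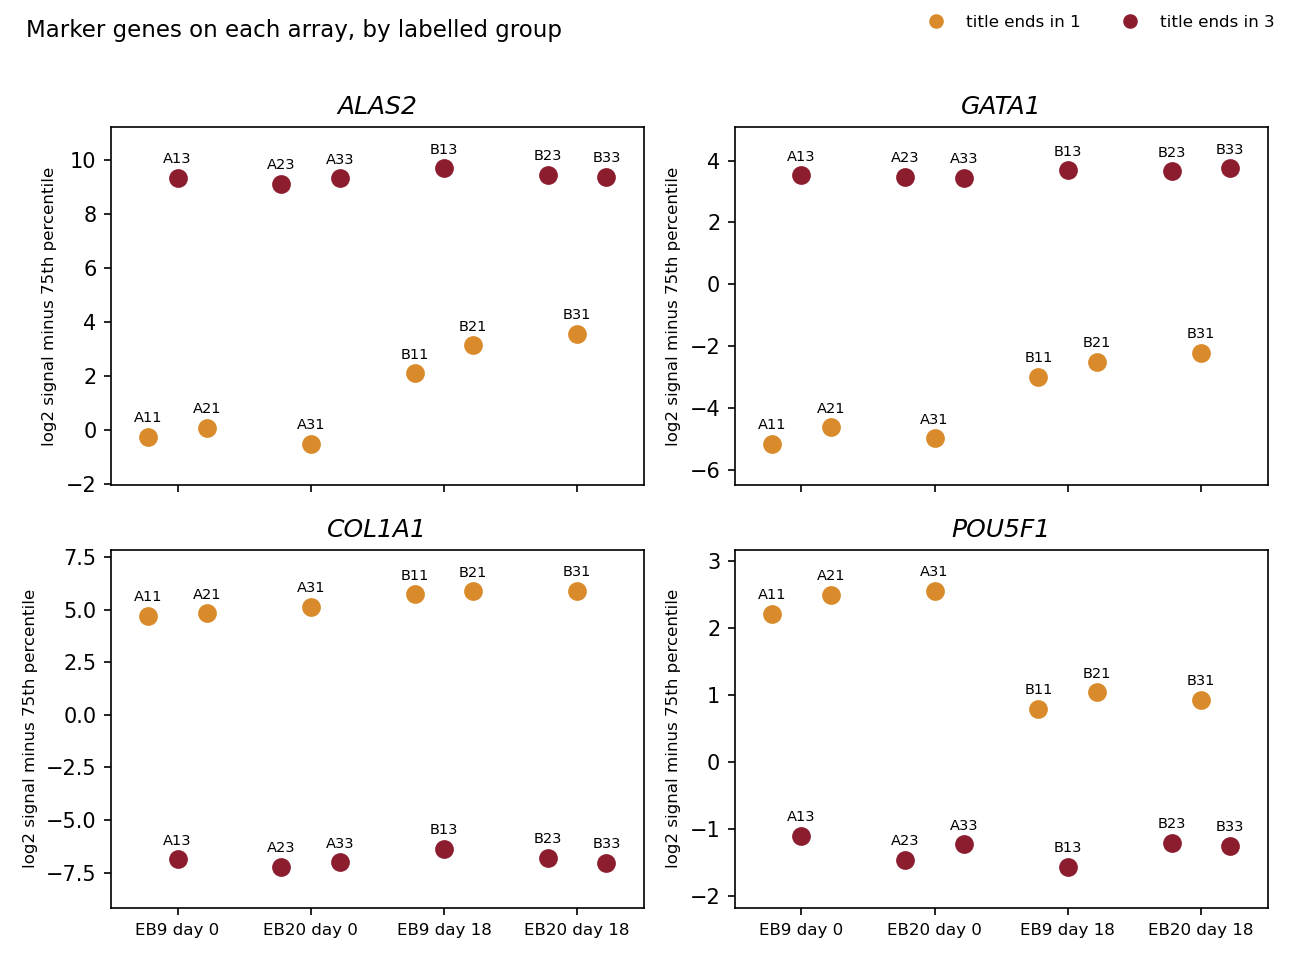
Level of ALAS2, GATA1, COL1A1 and POU5F1 on each of the 12 arrays (y axis, log2 signal minus the 75th percentile of the array), placed by labelled group (x axis) and coloured by the last digit of the title. Every labelled group holds both colours, and for ALAS2 the digit 3 arrays ran from 9.10 to 9.68 against -0.51 to 3.54 for digit 1.

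Across probes, 2 arrays with the same last digit correlated at r = 0.953 to 0.997, and 2 arrays with different digits at 0.726 to 0.763. Spearman's rho ran from 0.952 to 0.998 and from 0.727 to 0.762. These correlations are across probes, which are not independent replicates. Within a labelled group, arrays of different digits correlated at 0.735 to 0.761. Probes well above background numbered 33946 to 34719 on digit 1 arrays and 27567 to 29085 on digit 3 arrays. Globin probes took 0.0387 to 1.49% of the signal on digit 1 arrays and 3.44 to 5.63% on digit 3 arrays.

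**Figure D2:**
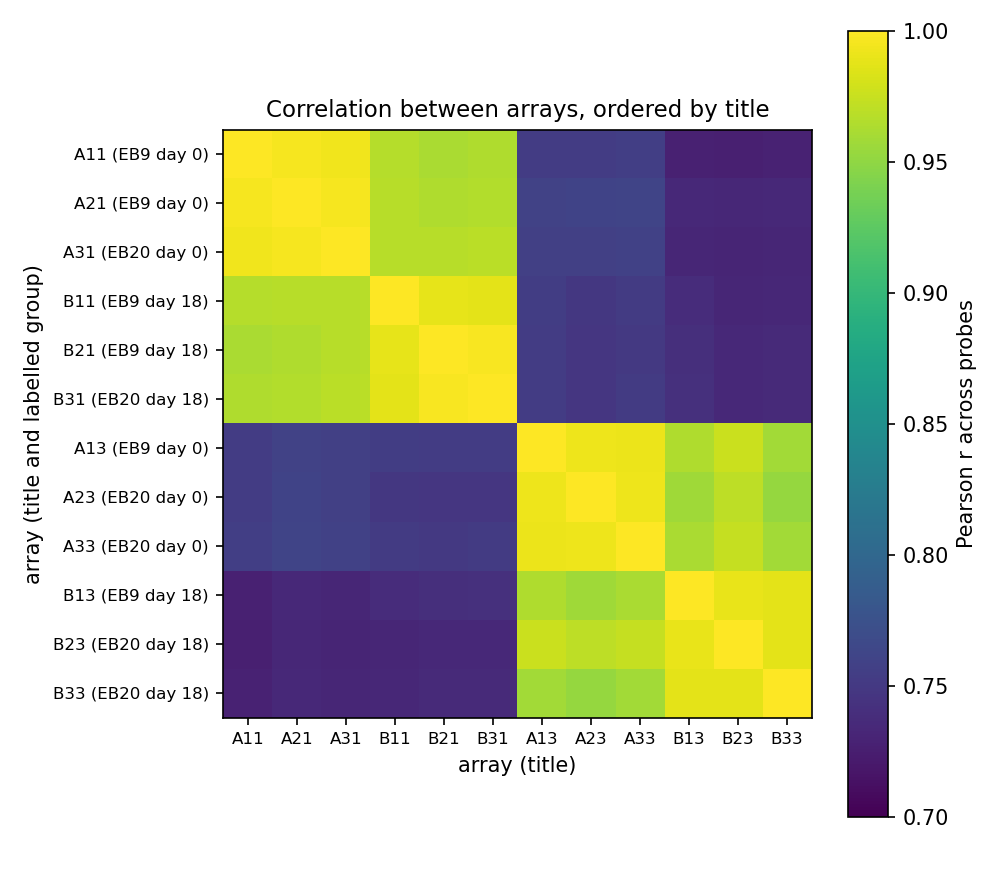
Pearson correlation across probes between every pair of the 12 arrays, named by title with the labelled group in brackets and ordered by title letter and last digit; the colour gives r. The 2 blocks of 6 arrays that share a last digit hold r from 0.953 to 0.997, against 0.726 to 0.763 between the blocks.

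As labelled, the comparison of day 18 with day 0 in EB9 asks which genes changed over erythroid culture. By title it sets B11, B13 and B21 against A11, A13 and A21, so the same last digits occur on each side. It is thus also a comparison of title letter B with A, and the labelled day cannot be told apart from the letter. Its largest rises included genes of white blood cells. CST7, a protease inhibitor of leukocytes, rose at least 8.87-fold (adjusted p = 0.00252), a bound, since its probe was not well above background on the day 0 arrays. Such a bound, used for all genes of that kind, sets the mean of the group with signal against the lowest level that passed as well above background on the arrays of the other group. LTF, an iron-binding protein of neutrophil granules, rose by 6.12 ± 0.76, measured against day 0 arrays of which 1 was well above background. The leukocyte surface gene CD48 rose by 3.91 ± 0.54 and CD37 at least 6.90-fold, and IL7R, a receptor of lymphoid cells, by 3.50 ± 0.52. VAV1, a signalling protein of blood cells, rose by 3.74 ± 0.54, CYTIP by 4.71 ± 0.65 and the natriuretic peptide gene NPPA, with the same limit as LTF, by 3.52 ± 0.49. ZC3H7B changed by -1.32 ± 0.20, the 1 gene called lower. The largest adjusted p among these was 0.0455.

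In the same comparison, limma called 33 of 21580 genes, 32 higher and 1 lower. No gene of the erythroid lists was called: 0 of 9 measured globins were called, and HBB, the adult beta globin, changed by 5.87 ± 4.20, which was not called. HBB stood at -5.64, 8.22 and -3.16 on A11, A13 and A21 and at -0.55, 10.18 and 7.40 on B11, B13 and B21. It was higher at day 18 for each shared title number, while its error spans both digits. The lack of calls thus does not show that red cell genes stayed level. The monocyte and macrophage list had a median change of 3.42 over 16 genes, with 0 called and 14 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.44e-26; adjusted p = 0.0181 with an estimated correlation). The granulocyte and mast cell list had a median of 3.95 over 10 genes, with 0 called and 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.76e-14; adjusted p = 0.0134 with an estimated correlation). The megakaryocyte and platelet list (1.30; adjusted p = 0.0134 with an estimated correlation), the lymphoid list (0.87; adjusted p = 0.0420 with an estimated correlation) and the hematopoietic stem and progenitor list (0.82; adjusted p = 0.0317 with an estimated correlation) also passed both tests. The count was 0 with normexp background correction, under which CST7, CD37 and NPPA turned to -0.20, -0.38 and -0.19, and 0 with quantile normalization, in the deposited value table, with the filter over all 12 arrays or with only the groups compared. It was 4396 with array weights, 1764 with the last title digit as a covariate and 319 with slide as a random block. It also rested on single arrays: leaving out 1 array at a time gave 153 genes without EB9 day 0 replicate 2, 30 without EB20 day 18 replicate 2, 13 without EB20 day 0 replicate 2 or EB20 day 18 replicate 1, 2 without EB9 day 18 replicate 2 or EB20 day 18 replicate 3, and 1 when any 1 of the other 6 was left out. Title numbers are shared by a day 0 and a day 18 array, and blocking on them gave 117 genes; the arrays of each day lay on 1 slide, so slide and day could not be separated.

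In EB20, the few genes called between arrays labelled day 18 and day 0 included some of white blood cells. This comparison too is one of title letter B with A, with the same last digits on each side. CST7 rose at least 5.21-fold (adjusted p = 0.0120). CD33, a surface lectin of myeloid cells, rose by 3.25 ± 0.39, LAT2, an adaptor of immune receptors, by 2.84 ± 0.31, and NCKAP1L, an actin regulator of blood cells, at least 8.12-fold. SQOR, a mitochondrial sulfide oxidase, rose by 4.26 ± 0.50, MLC1 by 3.50 ± 0.47 and NPPA at least 3.92-fold. The largest adjusted p of these was 0.0448, and limma called 13 of 21580 genes, all higher. HBB changed by 5.66 ± 4.20 (adjusted p = 0.931), and 0 of 9 globins were called. Here too HBB was higher at day 18 for each shared title number. It stood at 6.37, -3.73 and 7.81 on A23, A31 and A33 and at 9.89, 7.53 and 10.01 on B23, B31 and B33. The monocyte and macrophage list (2.78, 0 of 16 genes called, 10 higher and 0 lower adjusted over the list alone) passed camera (adjusted p = 3.67e-15) but not with the correlation estimated (adjusted p = 0.0837 with an estimated correlation). The granulocyte and mast cell list (2.90, 0 of 10 called, 2 higher and 0 lower adjusted over the list alone) likewise passed only the first (1.51e-07; adjusted p = 0.0837 with an estimated correlation). The count was 0 with normexp or with only the groups compared, and 2 with quantile normalization or in the deposited value table; it was 6997 with array weights, 3645 with the last title digit as a covariate and 43 with slide as a random block. Leaving out 1 array at a time gave 44 genes without EB9 day 0 replicate 2, 41 without EB20 day 0 replicate 2, 11 without EB20 day 18 replicate 1, 7 without EB9 day 18 replicate 2 and 5 without EB9 day 0 replicate 3. It gave 0 without EB20 day 0 replicate 1 or EB20 day 18 replicates 2 or 3, and 1 when any 1 of the other 4 was left out. Blocking on the shared title numbers gave 111 genes, and slide as a fixed block gave 0.

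Between the arrays labelled EB20 and EB9 at day 18, HBB changed by 3.46 ± 4.20 (adjusted p = 0.902). HBB stood at 5.68 ± 5.57 (SD, n = 3) on the arrays labelled EB9 day 18 and at 9.14 ± 1.40 on those labelled EB20 day 18. The lower EB9 mean rested on array B11, at -0.55, against 10.18 on B13 and 7.40 on B21. The erythroid membrane list had a median of 2.28 with 0 of 24 genes called and 0 higher and 0 lower adjusted over the list alone (9.62e-05 by camera; adjusted p = 0.444 with an estimated correlation). limma called 0 of 21580 genes at day 18, with 70 at an unadjusted p under 0.05. At day 0, limma called 0, with 36 at an unadjusted p under 0.05, and HBB changed by 3.68 ± 4.20. The difference between EB20 and EB9 in the day 18 versus day 0 change likewise gave 0 genes, with 24 at an unadjusted p under 0.05. Camera moved 14, 14 and 8 of 30 lists in these 3 comparisons, and 0, 0 and 0 with an estimated correlation. Fry moved 0, 0 and 0, against 7 lists for day 18 versus day 0 in EB9 and 6 in EB20. With limma's array weights, which let some arrays count for less, the counts were 14674, 18041 and 5209. Every other setting run gave 0. Most EB9 arrays have titles that end in 1 and most EB20 arrays titles that end in 3. Weights that discount the odd array of a group can thus bring in the difference between the digits. These counts are therefore no evidence of a difference between EB20 and EB9.

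Because the data split by title, the 12 arrays were also compared by title letter (A or B) and last digit, as title sets A-1, A-3, B-1 and B-3 of 3 arrays each. The split by last digit was predicted before the data were examined; all other comparisons of title sets were chosen after seeing the data. The titles do not say what a letter or a digit stands for.

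Red cell genes were far higher on digit 3 than on digit 1 arrays, in both letters. In letter A, HBB (chromosome 11, 5203294 to 5203353, probe position on hg18) rose by 11.64 ± 1.77 (adjusted p = 1.06e-04), and in letter B by 5.23 ± 1.77 (0.0177), or by 2.56 without array B11 (EB9 day 18 replicate 1). All 9 measured globins rose in both, 9 higher and 0 lower adjusted over the list alone, with medians of 8.08 in A and 4.60 in B (0.00169 and 0.00786 by camera; adjusted p = 0.341 in A and 0.393 in B with an estimated correlation). The embryonic globins HBE1 and HBZ rose by 7.06 ± 0.29 and 7.16 ± 0.23 in A and by 4.51 ± 0.29 and 4.60 ± 0.23 in B. Probes of HBA1 and HBA2, and of HBG1 and HBG2, can read each other's transcripts. Quantile normalization ended the call of the globin list in letter B, with a median of 3.27 (adjusted p = 0.0655) and 7 genes higher, HBB and HBG1 not among them. ANK1, an anchor protein of the red cell membrane, rose by 7.82 ± 0.17 in B. Of 24 erythroid membrane and blood group genes, 23 rose and 1 fell in each letter, 23 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.96e-09 in A and 1.53e-09 in B; adjusted p = 0.216 in A and 0.216 in B with an estimated correlation).

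Heme synthesis and iron handling genes rose in full, 21 of 21 in each letter, 21 higher and 0 lower adjusted over the list alone (camera adjusted p = 6.47e-09 and 1.66e-09; adjusted p = 0.216 in A and 0.216 in B with an estimated correlation). ALAS2 (chromosome X, 55052230 to 55052289) rose by 9.48 ± 0.31 in A and 6.58 ± 0.31 in B, SLC25A37, the mitochondrial iron importer, by 6.71 ± 0.09 and 6.41 ± 0.09, and AHSP, the alpha globin chaperone, by 10.79 ± 0.67 and 8.96 ± 0.67. Of 16 erythroid transcription factors, 13 rose and 2 fell in A, 15 and 1 in B (higher and lower adjusted over the list alone: 13 and 2 in A, 15 and 1 in B; 3.93e-04 and 8.93e-06 by camera; adjusted p = 0.221 in A and 0.216 in B with an estimated correlation). GATA1 (chromosome X, 48535797 to 48536559) rose by 8.41 ± 0.19 and 6.27 ± 0.19, KLF1 by 7.68 ± 0.23 and 6.89 ± 0.23 and GFI1B by 8.64 ± 0.17 and 6.87 ± 0.17. Of 22 organelle clearance genes, 19 rose and 1 fell in A and 22 rose and 0 fell in B (higher and lower adjusted over the list alone: 19 and 1 in A, 22 and 0 in B; 2.15e-04 and 5.72e-07 by camera; adjusted p = 0.221 in A and 0.216 in B with an estimated correlation). TRIM58, a ubiquitin ligase of late erythroblasts, rose by 7.65 ± 0.61 and 8.02 ± 0.61, the survival gene BCL2L1 by 3.96 ± 0.11 and 4.95 ± 0.11, and the autophagy gene MAP1LC3B by 4.37 ± 0.18 in B.

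The enucleation cytoskeleton and chromatin list went both ways. In A, 12 of 27 genes rose and 7 fell, and in B 15 and 7 (higher and lower adjusted over the list alone: 12 and 7 in A, 15 and 7 in B), and the list passed camera in neither (0.658 and 0.127). Its median in A was 0.07, and -0.21 under quantile normalization. KMT5A, a histone methyltransferase, rose by 2.83 ± 0.09 and 2.87 ± 0.09, and PLEK2, an actin-binding protein, by 3.03 ± 0.50 and 5.37 ± 0.50. The intermediate filament gene VIM changed by -5.97 ± 0.32 and -3.61 ± 0.32, and the formin DIAPH2 by -3.86 ± 0.14 and -3.61 ± 0.14. Of 20 DNA replication genes, 14 rose and 1 fell in A and 20 rose and 0 fell in B (higher and lower adjusted over the list alone: 14 and 1 in A, 20 and 0 in B; 0.0260 and 8.93e-06 by camera). Of 23 mitosis genes, 5 rose and 1 fell in A and 23 rose and 0 fell in B (higher and lower adjusted over the list alone: 3 and 1 in A, 23 and 0 in B; 0.561 and 3.89e-06 by camera). The mitotic kinase AURKA rose by 2.21 ± 0.10 and 3.19 ± 0.10, RRM2, which makes deoxyribonucleotides, by 4.04 ± 0.19 in B, and UBE2C changed by -1.46 ± 0.20 in A. With the correlation estimated, DNA replication and mitosis passed in neither letter (adjusted p = 0.696 to 0.899 in A and 0.384 to 0.393 in B with an estimated correlation), and under quantile normalization DNA replication no longer passed in A and the mitosis median in A turned to -0.19.

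Genes of embryonic lineages fell on digit 3 arrays. TTR (chromosome 18, 27432718 to 27432777), a carrier protein made by liver and yolk sac, fell at least 4992-fold in A, and AFP fell at least 667-fold in A and 1372-fold in B. COL1A1 fell at least 1690.3-fold and 2756-fold. The neural factor ZIC1 fell at least 417-fold and 384-fold, and KDR, an endothelial receptor, at least 83.2-fold and 63.0-fold. POU5F1 changed by -3.69 ± 0.14 and -2.26 ± 0.14. In letter A, the genes that fell were 17 of 19 endoderm and liver, 15 of 17 stromal and smooth muscle, 15 of 17 neural, 13 of 15 endothelial, 14 of 15 epithelial and trophoblast, 12 of 16 pluripotency and 24 of 28 HOX genes, with the same counts adjusted over the list alone. In letter B, they were 16, 15, 15, 12, 12, 10 and 23; adjusted over the list alone, the epithelial count was 13 and the rest did not differ. The largest camera adjusted p over these 7 lists was 0.00313 in A and 0.0129 in B, and none passed with the correlation estimated (adjusted p = 0.216 to 0.221 in A and 0.216 to 0.296 in B with an estimated correlation). Of 11 embryonic and fetal RNA-binding program genes, 1 rose and 9 fell in A and 2 rose and 9 fell in B (higher and lower adjusted over the list alone: 1 and 9 in A, 2 and 9 in B; 0.00524 and 0.0151 by camera; adjusted p = 0.221 in A and 0.296 in B with an estimated correlation), with HMGA2 down at least 547-fold and 345-fold.

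Stress and housekeeping genes moved between the digits as well. Of 16 p53 targets, 14 rose and 2 fell in A and 12 rose and 1 fell in B (higher and lower adjusted over the list alone: 14 and 2 in A, 12 and 1 in B; 0.00202 and 0.00297 by camera; adjusted p = 0.245 in A and 0.296 in B with an estimated correlation), with GADD45A up 3.34 ± 0.11 and 3.31 ± 0.11. Of 19 hypoxia and glycolysis genes, 2 rose and 14 fell in A and 2 rose and 17 fell in B (higher and lower adjusted over the list alone: 2 and 14 in A, 2 and 17 in B; 0.0260 and 0.00335 by camera; adjusted p = 0.547 in A and 0.393 in B with an estimated correlation), with P4HA1, a collagen-modifying enzyme, at -3.77 ± 0.27 and -4.99 ± 0.27. Of 13 unfolded protein and amino acid stress genes, 8 rose and 2 fell in A and 10 rose and 1 fell in B (higher and lower adjusted over the list alone: 8 and 2 in A, 10 and 1 in B; 0.0278 and 0.0102 by camera; adjusted p = 0.379 in A and 0.304 in B with an estimated correlation), and quantile normalization ended both list calls. The direction of cytosolic ribosomal protein genes depended on scaling: their median was 1.04 in A and 0.59 in B, with 36 and 33 of 36 genes higher (higher and lower adjusted over the list alone: 36 and 0 in A, 33 and 1 in B; adjusted p = 0.292 in A and 0.395 in B with an estimated correlation), but -0.06 and -0.37 under quantile normalization. Oxidative phosphorylation genes had medians of 0.92 and 0.82, with 19 and 20 of 21 higher (higher and lower adjusted over the list alone: 19 and 0 in A, 20 and 0 in B; adjusted p = 0.216 in A and 0.216 in B with an estimated correlation), and 0.18 and 0.03 under quantile normalization. Of 13 early mesoderm genes, 1 rose and 9 fell in A and 2 rose and 8 fell in B (higher and lower adjusted over the list alone: 1 and 9 in A, 2 and 9 in B; 0.00853 and 0.0219 by camera; adjusted p = 0.221 in A and 0.296 in B with an estimated correlation). Of 15 cardiac genes, 2 rose and 11 fell in A and 2 rose and 12 fell in B (higher and lower adjusted over the list alone: 2 and 11 in A, 2 and 12 in B; 0.0251 and 0.0526 by camera; adjusted p = 0.226 in A and 0.304 in B with an estimated correlation). Quantile normalization ended the list call of early mesoderm in both letters and of cardiac genes in A.

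limma called 20631 of 25297 genes in A, 10993 higher and 9638 lower, and 21141 in B, 10225 and 10916. The median of all genes was 0.13 in A under the 75th percentile scaling and 0.23 under quantile normalization, and -0.06 and 0.10 in B, so changes of that size have no fixed zero. On every slide that held both digits, at least 99.1% of the genes called without the arrays of that slide moved the called way within it. Genes of the white blood cell lists were called as well, with unlike directions in the 2 letters. Under quantile normalization, 10 of 13 granulocyte and mast cell genes rose and 0 fell in A, and 5 rose and 5 fell in B (0.0328 and 0.905 by camera). Of 19 monocyte and macrophage genes, 12 rose and 2 fell in A, and 3 rose and 12 fell in B (0.154 and 0.0582 by camera). Of these 2 lists, only the granulocyte and mast cell list in A passed camera under that scaling. Under the main scaling, 0 of 30 lists passed in A or in B with the correlation estimated.

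Between the letters on digit 1 arrays, white blood cell genes were higher in B. DEFA3, a neutrophil defensin, rose by 9.33 ± 0.70, and S100A8, a calcium-binding protein of myeloid cells, by 8.63 ± 0.68 (adjusted p = 2.81e-05). The DEFA3 probe can also read DEFA1. S100A12 rose at least 262-fold, RETN at least 196-fold and VSIG4, a macrophage complement receptor, at least 43.5-fold. Monocyte and macrophage genes were higher in 19 of 19 cases (19 higher and 0 lower adjusted over the list alone), with a median of 3.80 (camera adjusted p = 2.96e-14; adjusted p = 0.165 with an estimated correlation). Granulocyte and mast cell genes were higher in 12 of 13 (12 higher and 0 lower adjusted over the list alone), with a median of 4.91 (1.14e-10 by camera; adjusted p = 0.0719 with an estimated correlation). MPO, an enzyme of neutrophil granules, rose by 6.35 ± 0.54 and PRTN3 by 6.37 ± 0.43. Megakaryocyte and platelet genes were higher in 14 of 15 (15 higher and 0 lower adjusted over the list alone; 5.11e-10 by camera), the 1 list that passed with the correlation estimated (adjusted p = 0.0288 with an estimated correlation), with the platelet chemokine PPBP up 5.25 ± 0.36.

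Red cell genes were also higher in B among digit 1 arrays. All 9 globins rose (9 higher and 0 lower adjusted over the list alone; 5.55e-06 by camera; adjusted p = 0.265 with an estimated correlation), HBB by 8.97 ± 1.77 and HBG1 by 3.84 ± 0.48. Array B11 stood apart within set B-1: its HBB level was -0.55 against 7.40 and 7.53 on the other arrays, and -4.18 ± 1.30 (SD, n = 3) in A-1. Erythroid membrane genes rose in 17 of 24 (17 higher and 0 lower adjusted over the list alone; 6.54e-08 by camera; adjusted p = 0.265 with an estimated correlation) and erythroid transcription factors in 9 of 16 (9 higher and 1 lower adjusted over the list alone; 0.00409 by camera; adjusted p = 0.324 with an estimated correlation), GATA1 by 2.36 ± 0.19. Cell cycle genes were lower in B: 20 of 20 DNA replication and 23 of 23 mitosis genes (0 higher and 20 lower adjusted over the list alone and 0 higher and 23 lower adjusted over the list alone), with medians of -1.06 and -0.98 (3.04e-13 and 3.71e-14 by camera; adjusted p = 0.265 with an estimated correlation). CCNB1, a mitotic cyclin, changed by -1.23 ± 0.15 and the replication factor GINS2 by -1.43 ± 0.18. Pluripotency genes fell in 10 of 16 (0 higher and 10 lower adjusted over the list alone; 1.31e-05 by camera; adjusted p = 0.0633 with an estimated correlation), with POU5F1 at -1.50 ± 0.14 and the RNA-binding gene LIN28A at -2.76 ± 0.31. APLNR, the apelin receptor, changed by -2.92 ± 0.18.

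Interferon and MHC class I genes were higher in B in 15 of 18 cases on digit 1 arrays (16 higher and 0 lower adjusted over the list alone; 3.58e-07 by camera; adjusted p = 0.316 with an estimated correlation), the peptide transporter TAP1 by 3.01 ± 0.26 and MX1 by 2.87 ± 0.27. Immediate early and heat shock genes were higher in 9 of 16 (11 higher and 1 lower adjusted over the list alone; 0.00277 by camera; adjusted p = 0.167 with an estimated correlation), FOSB by 2.12 ± 0.32. Lymphoid genes rose in 3 of 12 (3 higher and 0 lower adjusted over the list alone) and hematopoietic stem and progenitor genes in 6 of 14 (6 higher and 1 lower adjusted over the list alone), and neither list passed camera (0.102 and 0.0590). NKG7, of cytotoxic lymphocytes, rose by 4.36 ± 0.19 and PTPRC, the pan-leukocyte phosphatase CD45, at least 29.6-fold. limma called 7790 of 25297 genes, 4264 higher and 3526 lower in B. The share higher was 54.7%, and 43.7% under quantile normalization. With normexp background correction 259 genes were called, and 7855 once outlying backgrounds were replaced. No slide held both A-1 and B-1 arrays; with slide as a fixed block 422 genes were called, and every globin call ended; of the other genes given above for digit 1 arrays, RETN, MPO, PRTN3, PTPRC, APLNR, NKG7 and FOSB kept theirs. The block widened the errors, with S100A8 at 7.92 ± 1.48 and HBG1 at 3.96 ± 1.35, and the cell cycle changes shrank, with CCNB1 at -0.63 ± 0.28 and GINS2 at -0.88 ± 0.46. Without EB9 day 18 replicate 3 the count was 4868, without EB20 day 18 replicate 2 5111, and with those 2 arrays (B21 and B31) averaged 4981.

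**Figure D3:**
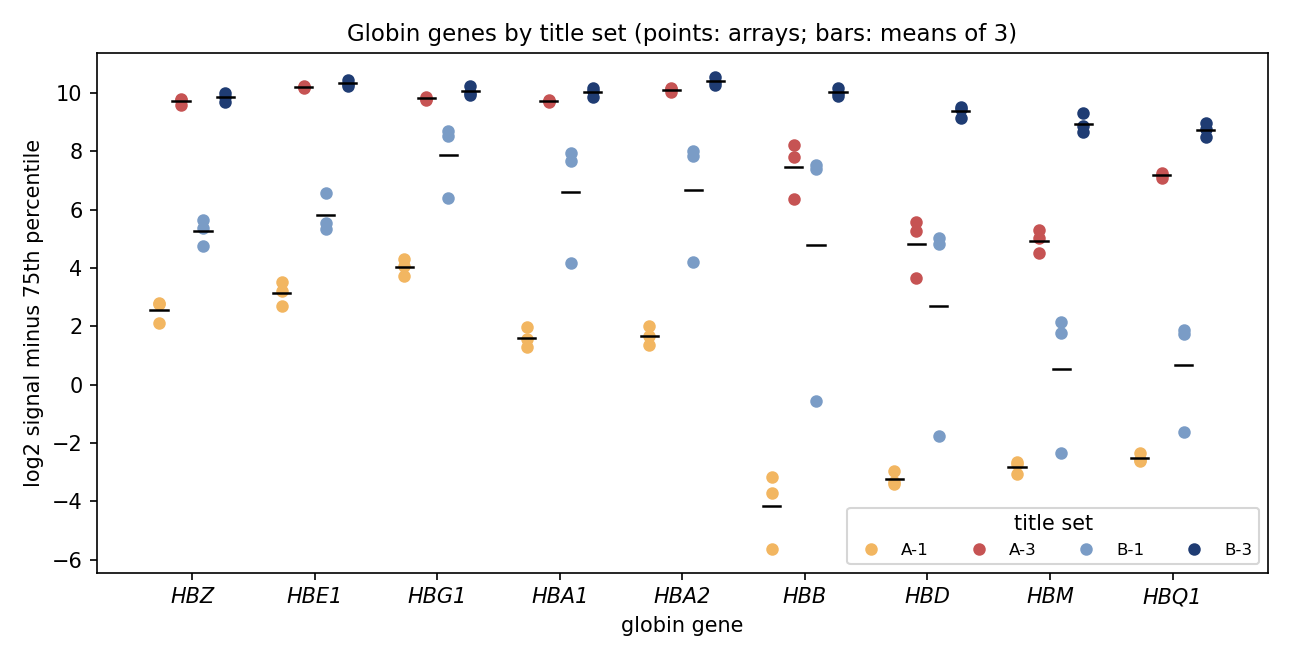
Levels of the 9 measured globin genes (x axis) on each array (points) of the title sets A-1, A-3, B-1 and B-3, as log2 signal minus the 75th percentile (y axis); bars are means of 3 arrays. HBB lay at -4.18 ± 1.30, 7.47 ± 0.97, 4.80 ± 4.63 and 10.03 ± 0.15 (SD) in these sets.

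On digit 3 arrays, genes of late red cell maturation were higher in letter B than in A. Of 22 organelle clearance and late maturation genes, 18 rose and 2 fell (18 higher and 2 lower adjusted over the list alone), with a median of 1.23 (camera adjusted p = 2.28e-07; adjusted p = 0.623 with an estimated correlation). XPO7, a nuclear export receptor, rose by 3.14 ± 0.12 (adjusted p = 4.39e-07), the autophagy genes GABARAPL1 and MAP1LC3B by 2.92 ± 0.18 and 2.42 ± 0.18, and TRIM58 by 3.01 ± 0.61. TMCC2, a membrane protein of erythroid cells, rose by 6.01 ± 0.53. Of 27 enucleation list genes, 10 rose and 2 fell (10 higher and 2 lower adjusted over the list alone), and the list did not pass camera (0.171). Among its changes were PLEK2 (2.92 ± 0.50), VIM (2.50 ± 0.32) and RAC2, a GTPase of blood cells (2.22 ± 0.23), with DIAPH2 at 0.78 ± 0.14.

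Among globins on digit 3 arrays, 2 of 9 were higher in B (2 higher and 0 lower adjusted over the list alone; 0.228 by camera). They were HBD, the delta globin, at 4.55 ± 1.44 (adjusted p = 0.0217) and HBM at 4.00 ± 0.92 (0.00417), and HBD lost its call in the deposited value table. HBB changed by 2.56 ± 1.77 (adjusted p = 0.245). Its levels ran from 9.89 to 10.18 on B-3 arrays and from 6.37 to 8.22 on A-3 arrays, without overlap. The error was pooled over all title sets, B-1 among them, where HBB ran from -0.55 to 7.53. The missing call thus does not show that HBB was level between the letters. HBE1 and HBZ changed by 0.13 ± 0.29 and 0.13 ± 0.23 and HBG1 by 0.24 ± 0.48, and all 3 turned sign under quantile normalization (-0.16, -0.09 and -0.04). Erythroid membrane genes rose in 13 of 24 (14 higher and 1 lower adjusted over the list alone; 0.00890 by camera), ACKR1, the Duffy blood group gene, by 1.84 ± 0.31 and the water channel AQP1 by 1.63 ± 0.32. RHCE rose by 1.74 ± 0.29, on a probe that can read RHD. Heme synthesis and iron genes rose in 11 of 21 (12 higher and 2 lower adjusted over the list alone; 0.0360), HEBP1 by 1.12 ± 0.14. Erythroid transcription factors rose in 8 and fell in 2 of 16 (8 higher and 2 lower adjusted over the list alone; 0.00972), with MYB, a factor of early progenitors, at 3.46 ± 0.34, E2F2 at 3.07 ± 0.17 and BCL11A, a repressor of fetal globin, at 2.81 ± 0.30; GATA1 changed by 0.22 ± 0.19 (adjusted p = 0.335). With the correlation estimated, these 4 lists did not pass (adjusted p = 0.623 to 0.755 with an estimated correlation).

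The granulocyte and mast cell list and the mitosis list were higher in B on digit 3 arrays too, as were KIT and GATA2. KIT, the stem cell factor receptor, rose by 3.64 ± 0.36 and GATA2, a progenitor factor, by 3.44 ± 0.19, but their hematopoietic stem and progenitor list did not pass camera (0.181; 6 rose and 3 fell of 14, 6 higher and 3 lower adjusted over the list alone). The mast cell genes TPSB2, CPA3 and HDC rose by 5.25 ± 0.36, 4.70 ± 0.63 and 4.28 ± 0.35, and MS4A2 at least 14.1-fold; tryptase probes can read TPSAB1 and TPSD1. Granulocyte and mast cell genes were higher in 9 of 13 (9 higher and 0 lower adjusted over the list alone; 0.00242 by camera), monocyte and macrophage genes in 14 of 19 (15 higher and 0 lower adjusted over the list alone; 9.90e-04) and mitosis genes in 20 of 23 (21 higher and 0 lower adjusted over the list alone; 2.11e-05), with no list passing when the correlation was estimated (adjusted p = 0.623 with an estimated correlation). RRM2 rose by 1.68 ± 0.19, the cyclin CCNA2 by 1.05 ± 0.16 and the proliferation marker MKI67 by 1.04 ± 0.22. DNA replication genes as a list did not pass (0.394 by camera; 4 rose and 2 fell of 20, 4 higher and 2 lower adjusted over the list alone). Interferon and MHC class I genes were higher in 11 of 18 (12 higher and 0 lower adjusted over the list alone; 0.00462 by camera; adjusted p = 0.623 with an estimated correlation), IFIT2 at least 5.83-fold. GKN2, a gastrokine, rose at least 16.2-fold, BIRC3, an inhibitor of cell death, at least 24.7-fold, and CDH1, the epithelial cadherin, by 4.93 ± 0.36.

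Ribosomal and glycolytic genes were lower in B on digit 3 arrays. Cytosolic ribosomal protein genes fell in 32 of 36 (0 higher and 32 lower adjusted over the list alone), with a median of -0.48 (1.89e-07 by camera; adjusted p = 0.623 with an estimated correlation); RPL22 changed by -1.02 ± 0.09 and RPL3 by -0.78 ± 0.08. Hypoxia and glycolysis genes fell in 12 of 19 (2 higher and 13 lower adjusted over the list alone; 0.0361 by camera; adjusted p = 0.643 with an estimated correlation), a list call that ended under quantile normalization. BNIP3, a mitophagy gene, changed by -2.51 ± 0.37 and LDHA, lactate dehydrogenase, by -1.71 ± 0.30. The imprinted genes H19 and DLK1 changed by -3.41 ± 0.31 and -1.42 ± 0.25, while their list, the embryonic and fetal RNA-binding program, did not pass camera (0.151; 1 rose and 6 fell of 11, 1 higher and 6 lower adjusted over the list alone). GATA6, an endoderm factor, was lower by at least 13.8-fold, and the immediate early gene EGR1 changed by -2.35 ± 0.14. limma called 13533 of 25297 genes, 5938 higher and 7595 lower. With slide as a fixed block 8326 were called, and the calls of TRIM58, PLEK2, HBD, HBM and LDHA ended. Only 1 slide held both letters, with arrays A33 and B33, so under the block the letter difference rests on those 2 arrays. A lost call there need not mean an effect of slide.

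**Figure D4:**
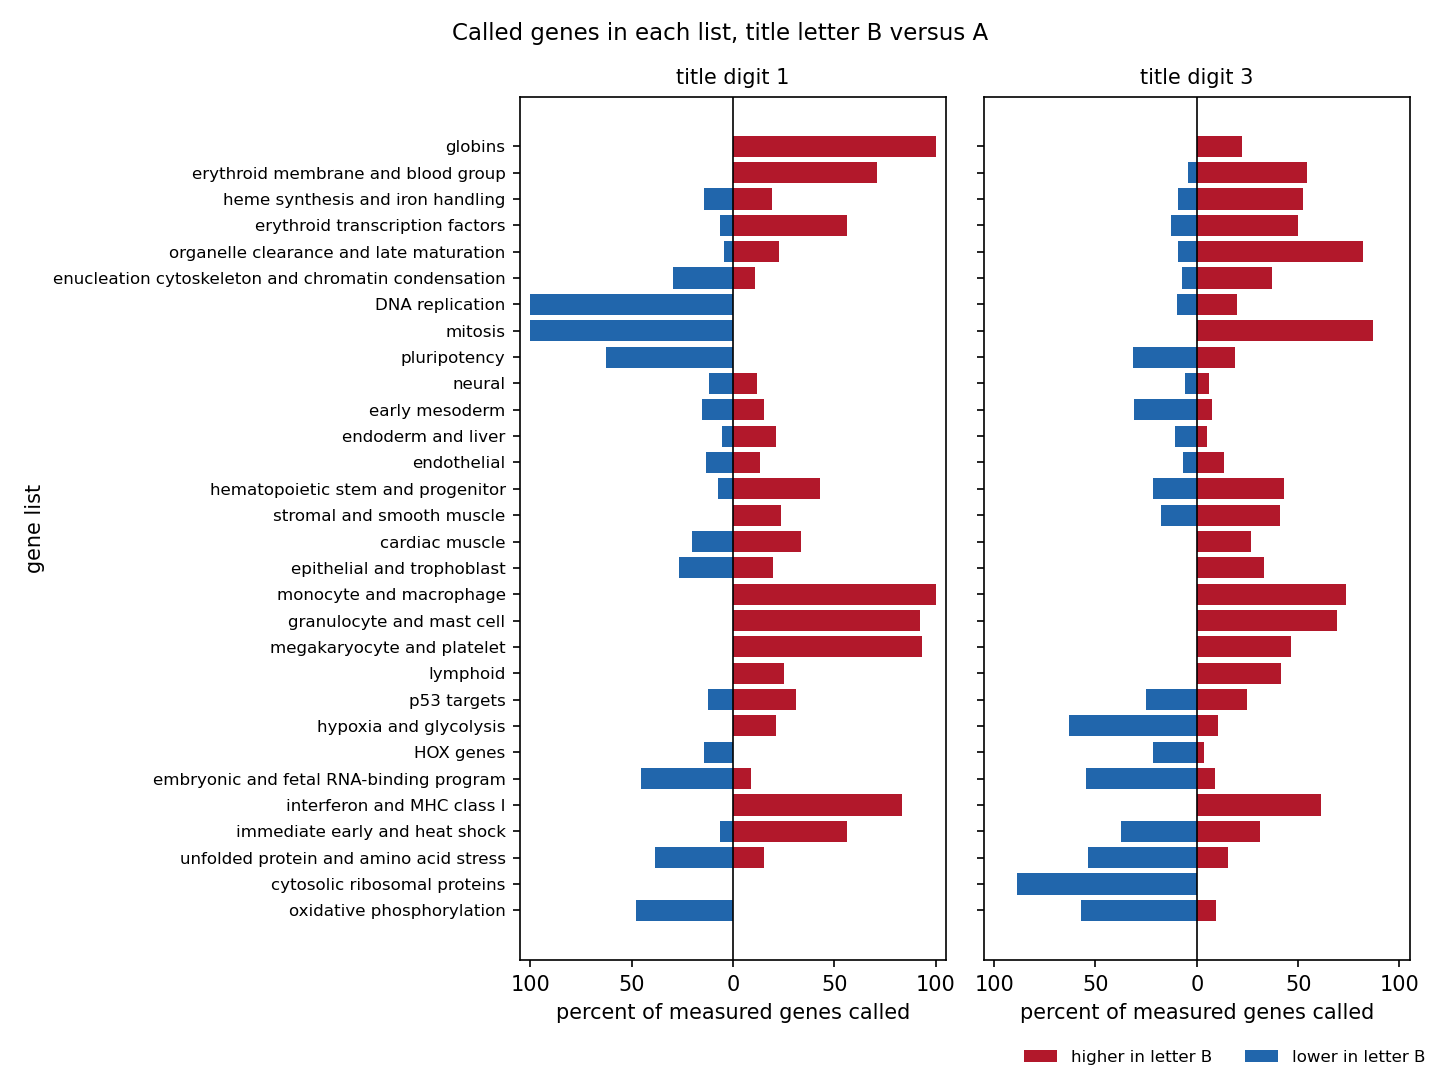
Percent of the measured genes of each of the 30 lists (y axis) called higher (red, to the right) or lower (blue, to the left) in letter B than in letter A, for digit 1 arrays (left) and digit 3 arrays (right). Mitosis genes were lower in 23 of 23 cases on digit 1 arrays and higher in 20 on digit 3 arrays; cytosolic ribosomal protein genes were lower in 32 of 36 on digit 3 arrays.

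The difference between the letters itself differed by digit for cell cycle genes. Mitosis genes shifted up in 23 of 23 and DNA replication genes in 19 of 20 cases in the test of that difference (23 higher and 0 lower adjusted over the list alone and 19 higher and 0 lower adjusted over the list alone; 2.82e-13 and 2.18e-08 by camera; adjusted p = 0.683 with an estimated correlation). MKI67 differed by 2.08 ± 0.31, CCNA2 by 2.03 ± 0.23 and RRM2 by 2.74 ± 0.27. Organelle clearance genes differed upwards in 14 of 22 (14 higher and 1 lower adjusted over the list alone; 1.75e-05 by camera; adjusted p = 0.676 with an estimated correlation), XPO7 by 3.06 ± 0.17 and GABARAPL1 by 2.87 ± 0.25. KIT differed by 4.25 ± 0.51 and E2F2 by 3.67 ± 0.23. Monocyte and macrophage genes differed downwards in 15 of 19 (0 higher and 15 lower adjusted over the list alone; 3.50e-04 by camera; adjusted p = 0.683 with an estimated correlation), and MPO, PRTN3 and VSIG4 by -7.22 ± 0.77, -7.26 ± 0.61 and -7.01 ± 0.83. HBE1, HBZ and ALAS2 differed by -2.55 ± 0.42, -2.56 ± 0.33 and -2.90 ± 0.43. limma called 11040 of 25297 genes, 4716 upwards and 6324 downwards.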

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

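All tests in this part were chosen after the results were seen, apart from the counts over other splits of the labelled groups. The difference between digit 3 and digit 1 in the title letter B versus A change stood out because its own test called 11040 genes: the effect of the letter differed between the digits. Genes with a higher B versus A change on digit 3 than on digit 1 arrays were KIT (4.25), E2F2 (3.67), XPO7 (3.06), GABARAPL1 (2.87), RRM2 (2.74), MKI67 (2.08) and CCNA2 (2.03). Those with a lower change were PRTN3 (-7.26), MPO (-7.22), VSIG4 (-7.01), ALAS2 (-2.90), HBZ (-2.56) and HBE1 (-2.55). Median differences were 1.63 for the mitosis list, 1.07 for DNA replication, 1.02 for organelle clearance, -2.56 for globins, -1.82 for monocyte and macrophage, -0.80 for megakaryocyte and platelet and -0.46 for cytosolic ribosomal proteins. With the correlation estimated, none of the 30 lists passed in this comparison. Of 100 splits of the arrays, 2 gave a count as high, the real one included. The other, with 13673 genes, also divided the arrays by title letter, with the letters exchanged in digit 1 or 3 only. In all, 17 splits called over 1000 genes. A count this high was thus rare among splits, but chance was not excluded for a comparison chosen after the data had been seen.

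A count of 0 is reached by any split, so the labelled counts of EB20 versus EB9 at day 18 (10 of 10 splits), at day 0 (10 of 10) and of the difference of changes (100 of 100) were not tested by other splits. The highest other counts were 11933, 8844 and 18636, each from the split by the last title digit. A set of 3 arrays against 3 makes too few splits for a share under 0.05, as in day 18 versus day 0 in EB9 (33 genes, 1 of 10 splits, highest other 0), in EB20 (13, 1 of 10, 0), title digit 3 versus 1 in letter A (20631, 1, 0) and B (21141, 1, 0), and title letter B versus A in digit 1 (7790, 1, 0) and digit 3 (13533, 1, 1).

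In every labelled group, the arrays split by the last digit of their titles. Slide as a batch is argued against: on the 4 slides that held both digits, at least 99.1% of the genes called without the arrays of a slide moved the called way within it. Cultures that varied without regard to their titles are argued against: of 100 pairs of a day 0 and a day 18 split, 1 called as many genes at both days as the split by digit, which was named before the data were examined. A source name that differs from what the tube held remains a hypothesis, weighed with the other observations.

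White blood cell and red cell genes were higher in B than in A on digit 1 arrays. Slide as a fixed block left the monocyte and macrophage median at 109.7% of its value without the block. No slide held both A-1 and B-1 arrays, so the block linked the letters only through the digit 3 arrays of 1 slide. It took each slide to shift digit 1 and digit 3 arrays alike, which was not tested. Slide therefore stays open for that list and for other genes. With the block all calls fell to 422, with wider errors. The CCNB1 change was -0.63 ± 0.28 with it, against -1.23 ± 0.15 without. Carry-over of RNA from the digit 3 arrays of letter B is argued against for white blood cell genes: 19.4% of the 31 list genes that rose lay higher in B-3 than in B-1. For red cell genes, 1 shared admixture on top of the A-1 level would add the same share of the B-3 level to each gene. The 75th percentile of that share was 5.33 times the 25th over 50 genes, with 20.8% for HBG1 and 0.930% for ALAS2. These percentiles were only 0.178% and 0.950%, and the lowest share was -2.52% (UROS). Small differences between the letters in a gene's own level could set this spread, so carry-over of red cell RNA stays open. A difference in cell make-up between the letters, if they stand for EB9 and EB20, may be the source, as an untested hypothesis.

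The late maturation, granulocyte and mast cell, and mitosis lists were higher, and the ribosomal list lower, in B than in A on digit 3 arrays, but none passed with an estimated correlation (adjusted p = 0.623 with an estimated correlation). On the 1 slide with an array of each letter, 95.4% of the 11855 genes called without those arrays moved the called way, which argues against slide as the whole cause. Under quantile normalization 90.8% of the calls kept their sign and call, so most calls do not hang on the choice between these scalings. Both adjust whole arrays, so a shift common to both was not tested. A biological difference between the cultures behind the letters may account for the pattern, as a hypothesis drawn from the same data and not tested.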

How the results depend on the processing

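Normexp with outlying backgrounds replaced, the last title digit as a covariate and all settings for the title sets were chosen after the data had been seen. Counts of called genes are given, and the cause of a change was not tested unless stated. For day 18 versus day 0 in EB9 (33 genes), the count was 0 with normexp, 0 with outlying backgrounds replaced, 0 with quantile normalization, 0 in the deposited value table, 1 with no filter, 0 with the filter over 12 arrays, 19 with trend and robust eBayes, 4396 with array weights, 319 with slide as a random block, 0 with only the groups compared (fewer samples), 117 with the title number as a replicate block and 1764 with the digit covariate. In EB20 (13), in the same order, it was 0, 2, 2, 2, 4, 4, 5, 6997, 43, 0, 111 (block) and 3645, and 0 with slide as a fixed block. Without 1 array each, the counts ran from 1 to 153 in EB9 and 0 to 44 in EB20. Array weights gave 14674 genes for EB20 versus EB9 at day 18, 18041 at day 0 and 5209 for the difference of changes, which were 0 in every other setting. The 2 labelled groups differ in their share of each last title digit, so weighted counts can reflect the digit.

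For title sets, normexp gave 11407 genes for digit 3 versus 1 in letter A, 11099 in B, 259 and 2266 for letter B versus A in digits 1 and 3, and 988 for their difference. Spots with an outlying background raised its fit on EB9 day 0 replicate 1 (5th percentile 10.76, and 5.92 once replaced) and less on EB20 day 18 replicate 2 (6.62, and 5.92); with them replaced the counts were 20601, 20703, 7855, 11073 and 9497. Letter B versus A in digit 1 gave 14963 with array weights, 422 with slide as a fixed block, 4981 with B21 and B31 averaged (fewer samples), and 4868 to 8790 without 1 array. In digit 3 it gave 8326 with slide as a fixed block, where the letter difference rests on arrays A33 and B33. Without 1 array the other title counts ran from 19855 to 20962, 20401 to 21079, 11820 to 13947 and 9281 to 11326. Among the calls, 54.7% were higher in B in digit 1, but 43.7% under quantile normalization; with outlying backgrounds replaced, the share higher in digit 3 went from 53.3% to 64.2% in A and from 48.4% to 59.4% in B. Gene list shifts fell from 57 to 5 with an estimated correlation in the labelled groups and from 79 to 1 in the title sets. By fry, 27 and 28 of 30 lists moved for digit 3 versus 1 in A and B. For the letters in digits 1 and 3 fry moved 16 and 22 lists, and 14 for their difference. In the 2 digit comparisons 81.6% and 83.6% of all genes were called, so most lists hold many called genes there.

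Values that changed sign under normexp were CST7 (-0.20), CD37 (-0.38) and NPPA (-0.19) in EB9, and KLF1 (-0.48), TUBB1 (-0.27), SPI1 (-0.31), OAS1 (-0.23), NPPA (-0.0731) and the enucleation (0.0632), ribosomal (0.30) and oxidative phosphorylation (0.0674) lists for letter B versus A in digit 1. In digit 3, HBG1, HBE1 and HBZ, not called, turned to -0.0353, -0.16 and -0.0913 under quantile normalization and -0.0457, -0.15 and -0.11 in the value table, and HBE1 to -0.0891 with the mean of its probes. The ribosomal list in digit 3 versus 1 of letter B turned to -0.37 and -0.36 in the same 2 settings. Of the genes followed through every setting, which are more than the text names, 49 of 51 kept their direction and call in every setting for digit 3 versus 1 in A, 49 of 53 in B, 6 of 57 and 39 of 70 for the letters in digits 1 and 3, and 0 of 10 in EB9. Probes near background limit the size of large changes: on digit 3 arrays 67.2 to 70.9% of probes were well above it.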

Other observations

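The hypothesis that the source names of some arrays differ from the samples their titles name had its tests written before the data were examined. The split of the 6 arrays labelled day 0 by the last title digit called 8844 genes, against 0 for the labelled split into EB9 and EB20, and the split of the 6 labelled day 18 called 11933, against 0. Both fit the prediction that the digit would call more genes than the labels. A candidate explanation is that the title letter names the EB group, that a last digit of 1 marks embryoid body cells and that a 3 marks erythroid culture. It would need only the source names to be wrong, not the arrays. On that reading, 4 of the 12 arrays (A11, A21, B23 and B33) carry a source name that matches their title. The source names A-D0, B-D0, A-D18 and B-D18 use A for EB9 and B for EB20, per the labels, and the titles use the same letters. No label says that the title letters mean the same, and the labelled comparisons of day and group would then mix both kinds of sample.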
